A study of Caenorhabditis elegans with 2 samples.

How the data were processed

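Gene expression was measured in 2 libraries, 1 from the wild type N2 Bristol and 1 from strain KU25 with the pmk-1(km25) deletion, both from young adults. Per the labels' protocols, worms were grown at 20 °C on agar plates with the *Escherichia coli* strain OP50 as food and then kept for 5 h at 35 °C on plates sealed in bags in a water bath. RNA was extracted with a guanidine and phenol reagent and cleaned on columns with DNase treatment. mRNA was selected on oligo(dT) beads, copied to cDNA with random hexamers and sequenced on an Illumina HiSeq instrument with a stated minimum of 10 M reads and more than 98% clean reads. The labels do not state a strand-specific library, so reads of overlapping genes on opposite strands cannot be told apart.

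The deposited values are counts of uniquely mapped reads per coding sequence ID, per the file headers, with no normalization. Beside them the authors give RPKM, which is the count scaled to coding length and to the library's listed reads. Recomputed from the counts, these RPKM values were matched with a largest relative error of 2.8e-08. The authors also give the percent of each coding length that reads covered, per the file headers. The aligner, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. All 9430 IDs had a length that is a multiple of 3, so untranslated regions were not counted. Because reads that map to more than 1 place were left out, counts of near-identical genes (major sperm proteins, vitellogenins, histones, glyceraldehyde-3-phosphate dehydrogenases) are uncertain, and an ID with low coverage holds reads from a small part of its sequence.

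The counts summed to 5.78 M reads in the wild type and 5.23 M in the mutant, equal to the totals in the headers. An ID had at least 1 read where it was listed, with 8820 IDs listed in the wild type, 9117 in the mutant and 8507 in both, and an ID listed in 1 library was given 0 reads in the other. That an unlisted ID had no reads is an assumption and was not tested, and values for genes with 0 reads rest on it. Against it stand genes expected to be abundant, such as unc-54, hsp-4, hsp-6 and hsp-70, which were listed in neither library. Among IDs listed in only 1 library, the highest count was 23 reads in the wild type and 50 in the mutant. A count of 0 allows up to 3 reads, which is 0.519 CPM (reads scaled to the library total) in the wild type and 0.574 in the mutant. The 10 most abundant IDs took 16.5% and 21.8% of reads. Intervals and this limit cover counting error only and treat each read as an independent molecule. Reads without molecular identifiers need not be independent molecules, so the intervals may be too narrow even for counting error.

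IDs were matched to the sequence names of the WBcel235 annotation, which was used for gene names and chromosome assignment only. Of the IDs, 9383 matched and 47 kept their own name, and IDs of 1 gene were summed, which gave 8730 genes. Of 19985 annotated protein-coding genes, 8643 (43.2%) had a listed ID. Genes without one, among them pmk-1, pmk-2 and several inducible heat shock genes, were not analysed here, so the check of the pmk-1 transcript that was planned gave no value.

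For each gene the ratio of CPM (mutant over wild type) was computed with an exact 95% interval (Clopper-Pearson, conditional binomial). A count of 0 gave a bound against 3 reads, which leaves out the counting error of the other library, so the end of the exact interval is given beside it. Log2 ratios used a prior of 0.5 reads in each library. A gene counted as higher or lower when it had at least 50 reads in at least 1 library, a ratio of at least 2 in that direction and an interval that excluded 1. With 1 library per genotype there are no residual degrees of freedom, so no test was made and no p-value is given. Before the data were examined, 36 gene lists were fixed, covering heat shock and chaperone genes, stress pathways, the p38 and JNK cascades, immune genes, detoxification, collagens, moulting, yolk, germline, tissue markers, ribosome, proteasome, mitochondria, histones and metabolism. Each list's median was placed among 10000 random lists of the same size drawn within 20 bins of read level. A further list of male markers was written after the other lists were seen and before its own values were.

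The genes named were set by a rule fixed at the same time. It takes pmk-1, pmk-2 and pmk-3, the 12 largest and 12 smallest ratios among genes at the level of 50 reads with at least 5 reads in each library, and up to 5 genes at that level with 0 reads in 1 library. It also takes up to 4 members of each described list with the largest absolute log2 ratio, all measured members of the inducible heat shock and PMK-1 target lists, and the 5 most abundant genes of each library. sip-1, hsp-17, gpd-4 and some of the paralogs in the closing section fall outside that rule and were chosen after their values were seen.

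Settings chosen before the data were examined and compared with the above were TMM factors, median-of-ratios factors, no level filter, a filter of 200 reads, a prior of 0.05 reads, a 1.5-fold threshold and the deposited RPKM with 1 added and a minimum of 5. After the data were seen, 3 more were added, which were counting per listed ID, scaling on somatic markers, and leaving out the sperm, oogenic and vitellogenin genes. The computation was tested on simulated counts for the 8730 genes of this comparison, of which 4972 passed the level. All 50 genes simulated at each of 4 fold changes (1/6, 1/3, 3 and 6) were recovered, and 0 of 4772 unchanged genes were called. The simulated counts held counting noise only, and the planted changes lay beyond the 2-fold threshold in genes with ample reads. These results check the computation and give no rate of false calls between populations. The intervals held the true ratio for 95.6% of genes, and 3 of 60 random lists of 15 members lay outside the percentiles 2.5 and 97.5. Those lists were drawn at random from independently simulated counts, so they do not show how lists of genes that vary together behave. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and the TMM factors came from edgeR 4.0.16 in R 4.3.3.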

Results

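Gene expression was measured by mRNA sequencing in whole young adult *Caenorhabditis elegans* of 2 genotypes, the N2 Bristol wild type and strain KU25, which carries the deletion allele pmk-1(km25). PMK-1 is a p38 mitogen-activated protein kinase of the worm, known for its role in innate immunity and stress responses. Both populations were grown at 20 °C and then held at 35 °C for 5 h before total RNA was extracted from whole-worm lysates. The design asks which transcripts differ between heat-stressed worms with and without PMK-1, with 1 library per genotype. Both were from heated worms, and unheated worms were not analysed here. The wild-type library held 5.78 M uniquely mapped reads and the mutant library 5.23 M, over 8730 genes with a read in at least 1 of them. Because each genotype has 1 library, no replicate error can be given and no test of genotype was made. Every ratio is mutant over wild type in CPM (reads scaled to the library total) with its exact 95% conditional binomial interval, which covers counting error only. For gene lists fixed before the data were examined, the median log2 ratio of the members with at least 50 reads in a library is given with its percentile among 10000 random lists of the same size and read level. Random lists hold genes drawn independently, while members of a list can vary together, so a percentile is a description and not a test. A list median counts each gene alike and need not follow the pooled reads of the list. These values describe 2 libraries. The median log2 ratio of all 5197 genes at that level was -0.33 when scaled to library totals. It was -0.24 with TMM factors and 0.002 with median-of-ratios factors. Some list medians are therefore also given relative to the median of all genes. Where they are not, a list median near -0.33 lies near that of all genes. With the libraries scaled on 33 markers of body tissues, a choice made after the data were seen, every log2 ratio was lower by 1.16, and ratios between 0 and 1.16 turned below 0.

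pmk-1 and pmk-2 were not analysed here, so the deletion itself was not checked, and genes used in the literature as targets of the kinase are given first. These immune genes were lower in the mutant library. C17H12.8, a gene with a CUB-like domain, had 516 reads in the wild type and 1 read in the mutant, which is 467-fold lower (interval 83.4 to 18464). dod-24 (C32H11.12), another CUB-like gene, had 66 reads against 1, which is 59.7-fold lower (10.3 to 2392), and the lysozyme gene lys-2 (Y22F5A.5) had 129 against 11, which is 10.6-fold lower (5.73 to 21.8). Of the 16 genes on this list, 12 had reads, all 12 had a lower CPM in the mutant, and the interval excluded a ratio of 1 for 8 of them. K08D8.5 had 23 reads in the wild type and 0 in the mutant, which is at least 6.93-fold lower against a limit of 3 reads for a count of 0, with a lower end of the exact interval at 5.2-fold. clec-67 (9 reads), dod-17 (8 reads) and sysm-1 (T24B8.5, 4 reads) also had 0 reads in the mutant. These 4 genes were not listed in the mutant library, which was taken as 0 reads and not tested, although the muscle myosin gene unc-54 was listed in neither library. C32H11.4 had 14 reads against 1 and irg-4 (F08G5.6) 14 against 3. For clec-85 (139 against 97 reads, 1.3-fold lower, 0.993 to 1.7), F35E12.8 (listed as cld-9, 23 against 17), F55G11.8 (5 against 2) and sysm-1, the intervals reached 1. The 4 members with at least 50 reads in a library had a median log2 ratio of -4.34 (percentile 0), which is -4 relative to all genes, and 3 of them were at least 2-fold lower. Markers of the intestine, where these genes are mainly expressed, lay in the opposite direction, with a median log2 ratio of 0.83.

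**Figure D1:**
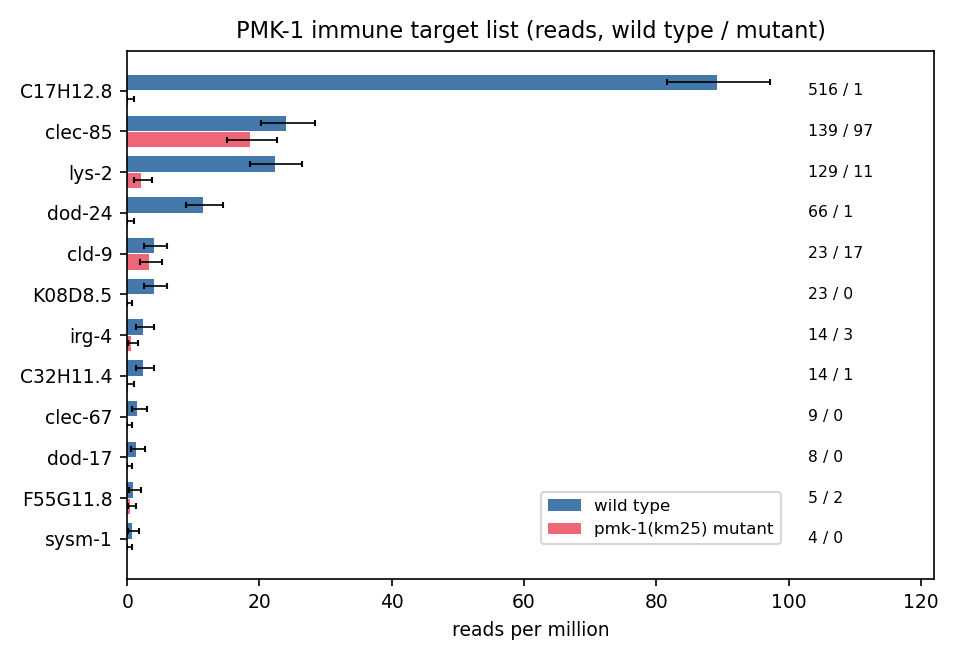
CPM, reads scaled to the library total (x axis) of the 12 PMK-1 immune target genes with reads, in the wild-type (blue) and pmk-1(km25) mutant (red) libraries. Bars show 1 library each, error bars are exact 95% Poisson intervals for counting error only, and the read counts stand at the right, from 516 against 1 for C17H12.8 to 4 against 0 for sysm-1.

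Within the p38 and JNK cascades, 7 of the 11 genes with reads passed the level of 50 reads, and the list had a median of -0.22 (percentile 41.6), which turned to 0.11 with median-of-ratios scaling. vhp-1 (F08B1.1), a MAP kinase phosphatase gene that restrains this signalling, had 51 reads against 15 and was 3.07-fold lower (1.7 to 5.89), from reads that covered 21.1% of the listed sequence in the wild type. The p38 gene pmk-3 (F42G8.4) had 35 reads against 63, 1.99-fold higher (1.3 to 3.1). The kinase kinase genes sek-1 (102 against 135 reads) and mek-1 (466 against 258 reads) were 1.46-fold higher (1.12 to 1.91) and 1.63-fold lower (1.4 to 1.91).

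Across the 5197 genes with at least 50 reads in a library, 914 were at least 2-fold higher in the mutant and 91 at least 2-fold lower, with an interval excluding 1. More genes had large ratios on the higher side, where 334 reached 4-fold and 247 reached 8-fold, while 8 genes were at least 4-fold lower. Among genes with at least 5 reads in each library, R09E10.2 had the largest ratio, with 9 reads against 420, 51.6-fold higher (26.9 to 114). Y37E11B.10 was 36.9-fold higher (5 against 167 reads), icmt-1 (F21F3.3) and F36D3.4 were each 32.7-fold higher (5 against 148 reads), and F58E6.5, clec-123, B0205.10, mstr-2, F13A7.1, T03F6.6, ttbk-8.1 and C09B9.4 were 22.9-fold to 25.5-fold higher. T09A12.1 had 0 reads in the wild type and 50 in the mutant, at least 18.4-fold higher against 3 reads, with a lower end of the exact interval at 14.4-fold and the same reading of an unlisted gene as 0. After lys-2, the genes with the smallest ratios and at least 5 reads in each library were R09E10.13 (68 against 6 reads, 10.2-fold lower, 4.47 to 28.9), H29C22.1 (438 against 97, 4.08-fold), C49G7.10 (152 against 34, 4.04-fold), mlt-10 (57 against 14, 3.68-fold) and C08F11.13 (155 against 41, 3.42-fold). They were followed by oac-14 (126 against 34, 3.35-fold), C24D10.5 (54 against 15, 3.26-fold), D1046.7 (52 against 15, 3.13-fold), vhp-1, rol-1 (121 against 36, 3.04-fold) and irg-8 (51 against 16, 2.88-fold). The irg-8 reads covered 8.35% of the listed sequence in the wild type and 6.63% in the mutant. Of 10 moulting genes with reads, mlt-10 was the 1 that passed the level, with a log2 ratio of -1.84 (percentile 2.58). With no level filter the median of the 10 genes was 0.04 (percentile 4.82), so no direction is given for that list. Of these calls, 90.9% were on the higher side. The share was 47.5% at a 1.5-fold threshold, where 1299 genes were higher and 1436 lower, and 8.1% with the scaling on somatic markers, where 311 were higher and 3528 lower. With the other 8 settings it lay between 90.3% and 98.0%. The most abundant transcript in both libraries was vit-5, with 7.37% of reads in the wild type and 11.21% in the mutant, followed by eef-1A.1, the translation elongation factor gene, and the chaperone genes hsp-1 and hsp-90, with vit-1.

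**Figure D2:**
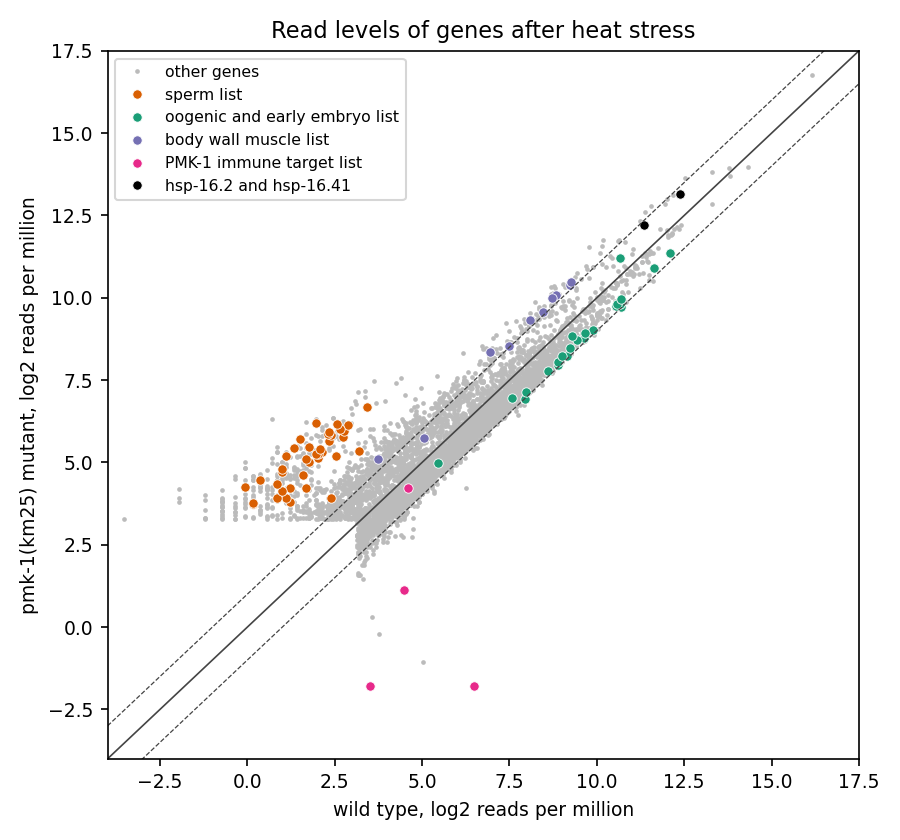
Log2 CPM in the wild-type (x axis) and pmk-1(km25) mutant (y axis) libraries for the 5197 genes with at least 50 reads in a library, with 0.5 reads added and members of 5 gene lists coloured. The solid line marks equal levels and the dashed lines 2-fold differences, and the 40 sperm genes lie above the upper line, while 22 of the 23 oogenic genes lie below the solid line.

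The series asks how PMK-1 influences the response to heat. The small heat shock protein genes hsp-16.2 (Y46H3A.3) and hsp-16.41 (Y46H3A.2), which heat induces strongly, were abundant in both libraries and higher in the mutant, with a direction that turned with the scaling on somatic markers. hsp-16.2 had 15133 reads against 24694, 1.8-fold higher (1.77 to 1.84), and hsp-16.41 had 30634 against 47241, 1.71-fold higher (1.68 to 1.73). They were the only members of the inducible list of hsp-16 and hsp-70 genes analysed here, and their median log2 ratio of 0.81, or 1.15 relative to all genes, lay at percentile 94.8. The 33 markers of intestine, muscle, pharynx, neurons and hypodermis had a median log2 ratio of 1.16 in the same libraries, and with that median set to 0 the hsp-16 value was -0.35. Of 6 other small heat shock protein genes, hsp-12.2 (3.73-fold, 2.86 to 4.93), hsp-12.3 (2.23-fold, 1.61 to 3.13) and hsp-43 (2.16-fold, 2 to 2.33) were at least 2-fold higher. hsp-12.6 was 1.88-fold higher (1.66 to 2.13), and sip-1 and hsp-17 had log2 ratios of -0.19 and -0.16. This list's median was 1.01 (percentile 99), or 1.34 relative to all genes, which turned to -0.15 with the scaling on somatic markers. With no level filter it lay at percentile 96.8 (8 genes), within the central 95% of random lists. Pooled over the 8 genes, reads were 17465 against 15641, a ratio of 0.99 (0.969 to 1.01). Most of these reads were from sip-1 (15823 against 12523).

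None of the 18 mainly constitutive cytosolic chaperones differed by 2-fold with library totals. Their median log2 ratio was -0.26 (percentile 44.9), or 0.07 relative to all genes. It turned to 0.07 with median-of-ratios scaling and to -1.42 with the scaling on somatic markers. hsp-90 (C47E8.5) had 81965 reads against 82539 and was 1.11-fold higher (1.1 to 1.12). hsp-1 (F26D10.3), the constitutive HSP70 gene, had 83855 against 69169 and was 1.1-fold lower (1.09 to 1.11). Its log2 ratio of -0.13 lies above the median of all genes, so with median-of-ratios scaling it lies above 0. The chaperonin subunit genes cct-1, cct-7 and cct-2 were 1.46-fold, 1.45-fold and 1.4-fold lower, and the ubiquitin ligase gene chn-1 was 1.57-fold lower (1.39 to 1.76). Neither the 16 genes of the endoplasmic reticulum stress list (median -0.23, percentile 70.05, 0.1 with median-of-ratios scaling) nor the 7 of the mitochondrial stress list (median -0.4, percentile 40.7) held a 2-fold difference with library totals. Relative to all genes the 2 medians were 0.10 and -0.06, and with the scaling on somatic markers they were -1.39 and -1.55. In the endoplasmic reticulum list, the kinase gene pek-1 was 1.56-fold higher (1.45 to 1.67) and its fellow sensor ire-1 was 1.42-fold lower (1.32 to 1.53). In the mitochondrial list, the chaperonin gene hsp-60 was 1.48-fold lower (1.38 to 1.58) and the prohibitin gene phb-2 was 1.55-fold lower (1.45 to 1.67). In both libraries the hsp-60 reads covered 37.7% of its listed sequence and the cct-7 reads 20.6%. All 31 proteasome subunit genes had log2 ratios below 0, with a median of -0.56 (percentile 4.53), or -0.23 relative to all genes. None differed by 2-fold with library totals, and the median was -1.72 with the scaling on somatic markers. The percentile was 1.82 with no level filter and 0.14 with the deposited RPKM. rpt-1, of the regulatory particle, was 1.71-fold lower (1.61 to 1.82) and pas-1, of the core, 1.65-fold lower (1.52 to 1.79).

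Transcripts of sperm and of the oogenic germline differed in opposite directions. All 40 sperm genes that passed the level were at least 2-fold higher in the mutant, with a median ratio of 9.97 and a median log2 ratio of 3.32 (percentile 100), or 3.65 relative to all genes. Most of these 40 genes passed the level through their mutant reads alone, which favours higher ratios. With no level filter the median log2 ratio of the 53 sperm genes with reads was 3.35 (percentile 100). These 53 genes took 0.016% of reads in the wild type and 0.158% in the mutant. ssp-16 was 21.9-fold higher (9.07 to 68.9), and the major sperm protein gene msp-142 had 22 reads against 380 and was 19.1-fold higher (12.4 to 30.9). spe-11, which encodes a sperm-supplied factor for the embryo, was 18.7-fold higher (11.3 to 33.2), and the sperm phosphatase gene gsp-3 was 17.9-fold higher (10.5 to 33.3). Reads of single msp genes are uncertain because the copies are near-identical and only uniquely mapped reads were counted. Of 23 oogenic and early embryo genes, 22 had log2 ratios below 0, with a median of -0.78 (percentile 0), or -0.45 relative to all genes, and 1 was at least 2-fold lower. That gene, egg-3, was 2.01-fold lower (1.83 to 2.21). The yolk receptor gene rme-2 had 9570 reads against 4439 and was 1.95-fold lower (1.88 to 2.02), and the RNA-binding protein genes puf-11 and oma-2 were 1.91-fold lower (1.79 to 2.04) and 1.89-fold lower (1.78 to 2.01). Both list medians kept their sign under TMM, median-of-ratios and somatic-marker scaling.

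Markers of most body tissues were higher in the mutant. In body wall muscle, 9 of 10 genes were at least 2-fold higher (median log2 ratio 1.22, percentile 100), or 1.56 relative to all genes. Among them were the tropomyosin gene lev-11 (2.68-fold, 2.45 to 2.93), the troponin T gene mup-2 (2.41-fold, 2.3 to 2.53) and the myosin light chain gene mlc-1 (2.38-fold, 2.24 to 2.53). In the pharynx, 5 of 5 were at least 2-fold higher (median 1.5, percentile 99.8), including the pharyngeal myosin genes myo-1 (3-fold, 2.81 to 3.21) and myo-2 (2.83-fold, 2.64 to 3.05). In neurons, 5 of 8 were (median 1.2, percentile 99.4), including the touch neuron genes mec-17 (2.96-fold, 1.85 to 4.9) and mec-12 (2.82-fold, 2.01 to 4.01). In the intestine, 2 of 6 were (median 0.83, percentile 99), asah-1 (3.78-fold, 3.16 to 4.54) and the protease gene cpr-1 (3.15-fold, 2.99 to 3.33). With no level filter the intestine list lay at percentile 92.1 (11 genes), within the central 95% of random lists. Its median turned to -0.32 when all somatic markers together were set to a median of 0. The hypodermis list had a median of 0.25 (4 genes, percentile 88.1, -0.91 with the scaling on somatic markers), from the adult collagen gene col-19 at 2.14-fold higher (2.1 to 2.19) to the transcription factor gene lin-26 at 1.86-fold lower (1.7 to 2.02).

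The vitellogenins, yolk proteins made in the intestine, were higher, though not with the scaling on somatic markers (-0.4), from 1.42-fold for vit-1 (1.4 to 1.43) and 1.52-fold for vit-5 (1.52 to 1.53) to 1.86-fold for vit-2 (1.83 to 1.9) and 2.02-fold for vit-6 (1.99 to 2.05). Their median was 0.75 (percentile 96.5) and together they took 9.18% of reads in the wild type and 14.2% in the mutant. The vit-2 reads covered 5.23% of its listed sequence, against 95.9% for vit-1 and 99.9% for vit-5 in the wild type. The cause of the low vit-2 coverage was not tested. vit-6 was counted on a listed sequence of 606 bases, against 4812 for vit-5. Among 47 cuticle collagens, 19 were at least 2-fold higher and 2 at least 2-fold lower (median 0.82, percentile 100, -0.34 with the scaling on somatic markers). With no level filter the median of the 99 collagens was 0.46 (percentile 86.2), and with the deposited RPKM it was 0.47 (percentile 97), both within the range of random lists. col-142 (3.41-fold, 3.15 to 3.7), col-98 (3.27-fold, 2.99 to 3.59), col-143 (3.09-fold, 2.95 to 3.24) and col-42 (3-fold, 2.87 to 3.15) had the largest ratios. All 5 protein genes of the mitochondrial genome that passed the level were at least 2-fold higher (median 1.41, percentile 99.99, 0.25 with the scaling on somatic markers), including the cytochrome oxidase gene COX3 (5087 against 15475 reads, 3.36-fold, 3.26 to 3.47). The 44 nuclear genes of the respiratory chain had a median of 0.11 (percentile 100, -1.05 with the scaling on somatic markers).

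**Figure D3:**
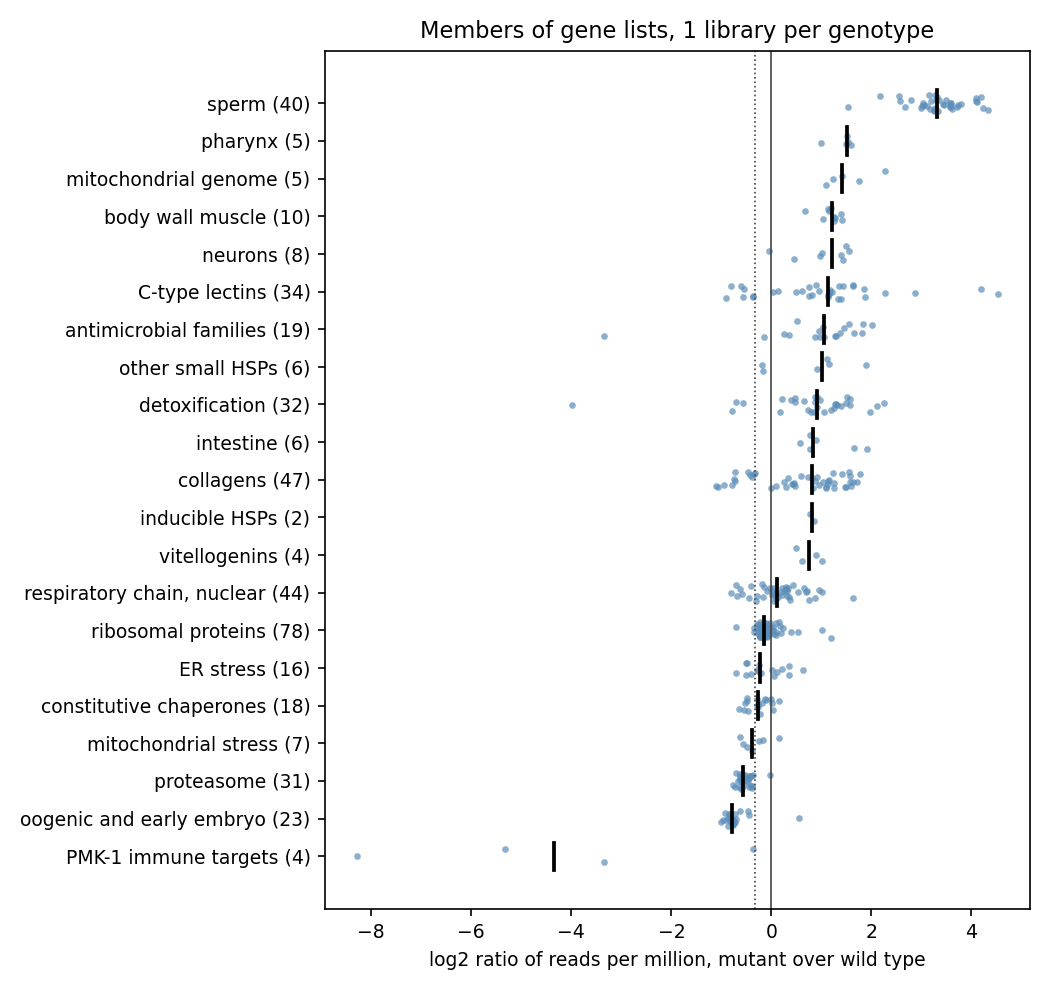
Log2 ratios of CPM, mutant over wild type (x axis), for the members of 21 gene lists with at least 50 reads in a library (points, number in brackets), with the list median as a black bar. The solid vertical line marks 0 and the dotted line the median of all genes at -0.33, and the lists run from PMK-1 immune targets at -4.34 to sperm genes at 3.32.

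Immune gene families were mostly higher in the mutant, with medians that turned below 0 with the scaling on somatic markers. Pooled over all members with reads, the ratio was 2.18 (2.12 to 2.23) for antimicrobial families and 1.08 (1.05 to 1.1) for C-type lectins. Of 19 lysozyme, saposin-like and antimicrobial peptide genes, 11 were at least 2-fold higher and lys-2, which is also a PMK-1 target, was the 1 at least 2-fold lower (median 1.06, percentile 99.99, -0.1 with the scaling on somatic markers). The saposin-like genes spp-1 (4.04-fold, 3.19 to 5.15), spp-5 (3.57-fold, 3.32 to 3.83) and spp-2 (3.51-fold, 2.87 to 4.32) had the largest ratios. Of 34 C-type lectin genes, among them the PMK-1 target clec-85, 18 were at least 2-fold higher and 0 lower (median 1.13, percentile 100, -0.03 with the scaling on somatic markers), led by clec-123 (25.22-fold, 10.5 to 79.1), clec-73 (18.7-fold, 11.6 to 31.9), clec-190 (7.52-fold, 4.68 to 12.7) and clec-52 (4.94-fold, 2.79 to 9.31). clec-123 and clec-73 are among the 213 genes outside the sperm list that were at least 8-fold higher, in a library where sperm genes had a median ratio of 9.97. In the list of ZIP-2 targets and intracellular pathogen response genes (4 genes, median 0.76, percentile 79.5, -0.39 with the scaling on somatic markers, -1.3 with a filter of 200 reads, which leaves zip-2), the bZIP transcription factor gene zip-2 had 1245 reads against 457 and was 2.46-fold lower (2.21 to 2.75), while irg-3 and skr-4 were 2.05-fold (1.33 to 3.21) and 2.04-fold higher (1.3 to 3.24).

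Among cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes, 14 of 32 were at least 2-fold higher (median 0.91, percentile 99.6, -0.25 with the scaling on somatic markers) and ugt-44 (F01D4.2) was lower, with 78 reads against 4, 17.6-fold (6.62 to 66.3). With the deposited RPKM the list lay at percentile 96.4 (40 genes), within the central 95% of random lists. The glutathione S-transferase genes gst-10 (4.8-fold, 3.25 to 7.29), gst-39 (4.37-fold, 2.71 to 7.34) and gst-24 (4-fold, 2.57 to 6.43) were higher. The 6 SKN-1-associated oxidative stress genes had a median of 0.72 (percentile 97.4, -0.44 with the scaling on somatic markers). Among them, gst-5 was 2.41-fold higher (1.83 to 3.19) beside gst-10. Of these 6 genes, gst-4, gst-5, gst-7 and gst-10 are also in the detoxification list, so the 2 lists are not independent. Of 11 genes used as targets of the insulin-pathway factor DAF-16, 5 were at least 2-fold higher (median 0.91, percentile 99.6). The median was -0.25 with the scaling on somatic markers. Among the 5 were the superoxide dismutase gene sod-3 (2.99-fold, 1.76 to 5.27) and the glyoxylate cycle gene icl-1 (4.18-fold, 3.29 to 5.36). The icl-1 reads covered 12.5% of its sequence in the wild type. Most of the 11 genes are also in the lists of other small heat shock proteins, antimicrobial families, antioxidant enzymes or glycolysis genes. This list is therefore not a separate result from those. The 10 antioxidant enzymes had a median of 0.09 (percentile 90.01, -1.07 with the scaling on somatic markers), with gpx-5 2.57-fold higher (2.21 to 2.99). The 6 hypoxia response genes had a median of 0.81 (percentile 92.0, -0.34 with the scaling on somatic markers), with cysl-1 2.74-fold (2.04 to 3.71) and phy-2 2.3-fold higher (1.53 to 3.53). The 4 osmotic and metal response genes had a median of 0.18 (percentile 69.1, -0.98 with the scaling on somatic markers).

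Lists of housekeeping, metabolic and signalling genes had medians between -0.57 and 0.7. The 78 ribosomal protein genes had a median of -0.15 (percentile 89.9, or 1.11 with the deposited RPKM), which turned to 0.18 with median-of-ratios scaling, with rpl-25.1 (2.27-fold, 2.11 to 2.44) and rpl-11.2 (2.01-fold, 1.89 to 2.15) the members at least 2-fold higher. The 28 glycolysis and citrate cycle genes had a median of 0.07 (percentile 99.8, -1.09 with the scaling on somatic markers), with 4 at least 2-fold higher and 1 lower. Besides icl-1, the higher genes were the glyceraldehyde-3-phosphate dehydrogenase genes gpd-3 (2.35-fold, 2.22 to 2.5) and gpd-2 (2.19-fold, 2.05 to 2.34) and the aldolase gene aldo-1 (2.37-fold, 2.16 to 2.6). The lower gene was their relative gpd-4, at 2.06-fold (1.79 to 2.36). The 36 fatty acid genes had a median of 0.7 (percentile 100, -0.46 with the scaling on somatic markers) and 9 of them were at least 2-fold higher, led by the acyl-CoA dehydrogenase genes acdh-8 (13.1-fold, 8.01 to 23) and acdh-4 (6.12-fold, 3.5 to 11.42). Like clec-123 and clec-73, acdh-8 is among the 213 genes outside the sperm list that were at least 8-fold higher. The 19 autophagy and lysosome genes had a median of 0.18 (percentile 99.6, -0.97 with the scaling on somatic markers) and no 2-fold difference, with the aspartic protease gene asp-1 1.86-fold higher (1.81 to 1.9). The 10 insulin signalling genes had a median of -0.51 (percentile 14.7), or -0.175 relative to all genes. It was -1.67 with the scaling on somatic markers, and no gene differed by 2-fold with library totals. The 13 apoptosis and DNA damage genes had a median of -0.57 (percentile 5.43), or -0.24 relative to all genes. Among them, clk-2 was 1.83-fold lower (1.64 to 2.04). Transcripts of the histone family mostly lack poly(A) tails, and which of the 11 genes that passed the level carry them was not tested. These 11 histone genes had a median of -0.11 (percentile 68.2), which turned to 0.23 with median-of-ratios scaling and to 0.74 (percentile 99, 6 genes) with a filter of 200 reads. Among them, his-24 was 3.01-fold higher (2.33 to 3.92) and his-64 was 2.36-fold lower (1.44 to 4).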

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

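Counting per listed ID, scaling on somatic markers and leaving out the sperm, oogenic and vitellogenin genes were chosen after the results were seen. The 914 higher genes became 1601 with no level filter, 389 with a filter of 200 reads, 1299 at a 1.5-fold threshold and 311 with the scaling on somatic markers. The 91 lower genes became 59 with TMM factors, 25 with median-of-ratios factors, 164 with no level filter, 32 with a filter of 200 reads, 1436 at a 1.5-fold threshold and 3528 with the scaling on somatic markers. The filters change how many genes are counted (8730 and 3462 in place of 5197), and a scaling factor moves every ratio alike. Of the 914 higher genes, 868 were also higher with the deposited RPKM and 311 with the scaling on somatic markers. The median of the PMK-1 target list stayed below 0, between -5.49 and -3.13 with at least 4 members, and at -8.28 with a filter of 200 reads, which leaves C17H12.8. The 1.5-fold threshold cannot move a median. The hsp-16 list lay between 0.81 and 1.15 except with the scaling on somatic markers (-0.35).

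With the scaling on somatic markers, 19 lists changed sign, by its construction, which lowers every log2 ratio by 1.16. The 11 of them that lay outside the central 95% of random lists had medians of -0.15 for other small heat shock proteins, -0.10 for antimicrobial families, -0.031 for C-type lectins, -0.25 for DAF-16 targets, -0.25 for detoxification genes, -0.34 for collagens, -0.32 for intestine markers, -1.05 for nuclear respiratory chain genes, -0.46 for fatty acid genes, -0.97 for autophagy and lysosome genes and -1.09 for glycolysis and citrate cycle genes. The sign also changed for 5 lists with median-of-ratios factors, for 2 with no level filter (p38 and JNK cascades 0.07, moulting 0.04) and for 2 with a filter of 200 reads (histones 0.74, ZIP-2 and pathogen response genes -1.3).

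Some lists moved across the edge of the central 95% of random lists with their sign kept, and the cause was not tested. With no level filter, collagens (percentile 86.2), intestine markers (92.1) and other small heat shock proteins (96.8) came to lie within it and the proteasome (1.82) outside. With the deposited RPKM, collagens (97) and detoxification genes (96.4) came to lie within it, and ribosomal proteins (1.11) and the proteasome (0.14) outside. Moulting (2.43) came to lie outside without the sperm, oogenic and vitellogenin genes.

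No paired analysis was possible because each genotype has 1 library and the labels give no replicate numbers, and for the same reason leaving out a library was not an option. The planned pmk-1 level gave no value under any setting. The moulting list had no member left with the filter of 200 reads or with RPKM. Of the 867 genes with 50 to 99 reads in their higher library, 293 counted as higher in the mutant, and genes at that depth have wide intervals.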

Other observations

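Of the tests given here, those of scaling, of the germline share as a source of the sperm difference, of the somatic share behind the hsp-16 genes and of both explanations for the PMK-1 targets were chosen after the results were seen, as were the paralogs.

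Some proteins are encoded by paralogs of which 1 was assigned mainly to the germline or embryo and another to the body. These assignments were not tested here. In 5 of these 6 proteins the copies differed in opposite directions with library totals. Median-of-ratios scaling raises the median of all genes from -0.335 to 0.002. With it, asg-1 (log2 ratio -0.171 with library totals) also lies above 0 and rpl-25.2 (-0.338) lies near 0. The ribosomal protein gene rpl-11.2 was 2.01-fold higher (interval 1.89 to 2.15) and its paralog rpl-11.1 was 1.63-fold lower (1.58 to 1.68). The ATP synthase genes asb-2 and asb-1, of which asb-1 is the germline copy, were 2.01-fold higher (1.9 to 2.13) and 1.63-fold lower (1.54 to 1.73). The glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 and gpd-3 were 2.19-fold and 2.35-fold higher, and gpd-1 and gpd-4 were 1.82-fold (1.64 to 2.03) and 2.06-fold lower (1.79 to 2.36), from uniquely mapped reads over 52.2% to 81.3% of near-identical sequences. rpl-25.1 was 2.27-fold higher and rpl-25.2 was 1.26-fold lower (1.23 to 1.3). asg-2 was 1.94-fold higher (1.67 to 2.25) and asg-1 1.13-fold lower (1.02 to 1.24). eef-1A.2, with 33 against 32 reads, did not differ detectably (1.07-fold, 0.638 to 1.8). Its reads covered 6.82% of its sequence in the wild type and 5.68% in the mutant. eef-1A.1 was 1.3-fold lower (1.29 to 1.31), with a log2 ratio of -0.376, near the median of all genes. The assignment of eef-1A.1 to the germline or embryo is uncertain. With so few reads of eef-1A.2, this pair gives no contrast between germline and body. With the scaling on somatic markers all of these ratios lie lower by 1.16 on the log2 scale, so that rpl-11.2, asb-2, asg-2 and gpd-2 also lie below 0, and the order within each pair stays.

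Sperm genes were higher, oogenic genes lower and somatic markers higher in the mutant library, and the medians of the sperm and oogenic lists lay 4.1 apart on the log2 scale, which no scaling factor can produce. A smaller germline share in the mutant worms is a candidate explanation for the oogenic and somatic parts, since X-linked genes in no list, which the germline uses little, had a median 0.97 above that of autosomal genes (388 genes at 0.56, 4203 at -0.41). It does not account for the sperm genes, germline transcripts with a median of 3.32, and of 213 genes outside the sperm list that were at least 8-fold higher, 0.0% lay on the X chromosome (exact 95% upper bound 1.72%) against 8.82% of the 5135 genes outside that list, consistent with spermatogenesis genes, which are rare there. Males among the mutant worms cannot be told apart from other sources of sperm transcripts, although the upper bound of the male marker ratio, 5.23, lies below the sperm ratio of 9.97. The bound set beforehand assumed that male markers multiply like sperm transcripts, which their 19 reads in the wild type, of untested origin, need not do, and none of the 6 genes reached 50 reads, and stage at harvest and genotype were not tested.

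hsp-16.2 and hsp-16.41 were higher in the mutant library. Their median lay at percentile 27.3 among the 33 somatic markers, of which 24 were higher, and at percentile 22.9 among the medians of all 528 pairs of these markers. A larger share of somatic RNA is therefore not excluded, which is no evidence for it, since the markers spread widely (quartiles 0.776 and 1.43). Whether heat induced these genes differently in the mutant was not tested, since no unheated library was analysed here.

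The PMK-1 target genes were lower in the mutant library. A lower intestinal share is argued against by the intestine markers, whose median lay 5.17 above that of the targets on the log2 scale, and counting noise by the pooled reads of the 12 genes (950 against 133), whose ratio had an upper bound of 0.186. What remains open is the loss of PMK-1 and any other difference between the populations, which 1 library per genotype cannot separate, so a dependence of these genes on PMK-1 under heat stays a hypothesis here.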
